A study of Mus musculus with 8 samples.

How the data were processed

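RNA from 8 single mouse hearts at E10.5, 4 Dbh-/- and 4 Dbh+/+, was hybridised to Mouse 430A 2.0 arrays, per the labels. Per the labels' protocols, age- and size-matched hearts were isolated after ultrasound and total RNA was extracted with Trizol. The authors' deposited signal values are MAS5 signals on a linear scale, per the file headers. The MAS5 version, the scaling target and the genome build are not stated. The deposited intensity values of the value table equal those of the whole-series export to within 5e-07, and no common scaling of the arrays is visible in them. Detection calls (Present, Marginal or Absent) come from the same export, per the file headers. The deposited fold value per probe set is a signed score, WT over KO, and negative where KO is higher, per the file headers. The authors' deposited p-value per probe set is called a Student test on signal intensity in the deposited legend. Recomputation gave the unequal-variance form of that test on linear signals, with differences of at most 2.51e-09, while the equal-variance form differed by up to 0.0476. The deposited quality report gives the fraction of probe sets called Present, the ratio of log intensity to log background, the 5' to 3' signal ratio of 2 control transcripts, the background intensity and the amplified cDNA mass, per the file headers.

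Probe sets were named through the platform annotation, with symbols updated by gene identifier. Of 22690 probe sets, 20393 had 1 symbol, 691 several and 1606 none, and only those with 1 symbol were named. Gene positions relative to Dbh came from a reference gene table (assembly GRCm38.p6), used only for which genes neighbour Dbh.

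The comparison was KO minus WT with limma (version 3.58.1, R 4.3.3, statmod 1.5.0), lmFit and eBayes with an intensity trend, on log2(signal + 16), with no further normalization and no covariate. Tested were probe sets called Present in at least 3 of the 8 arrays, control probe sets left out, 16292 in all. A call is a Benjamini-Hochberg adjusted p under 0.05. A gene took its tested probe set with the highest mean log2 signal. A list score is the mean over tested members of log2 signals centred per gene, and scores were compared by exact two-sided permutation tests over 70 assignments. Sets were 24 lists fixed beforehand with at least 5 tested members and 155 terms of 10 to 300 tested genes from the deposited annotation. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and the lists with fry. The lists were catecholamine synthesis and handling, adrenergic receptor and cAMP signalling, sarcomere, calcium handling and ion channels, cardiac transcription factors, natriuretic peptides and cardiac stress genes, retinoid metabolism and response, hypoxia-induced genes, glycolysis, oxidative phosphorylation, citrate cycle, fatty acid oxidation, cell cycle, p53 targets and apoptosis, integrated stress and unfolded protein response, immediate early and heat shock genes, and markers of endothelium, cushion mesenchyme, epicardium, erythroid cells, macrophages, liver and endoderm, neurons and neural crest, and branchial and skeletal muscle. A list of sex-linked genes was described and not tested as a set. The tests, samples, covariates, lists and alternatives were fixed before the data were examined, unless said otherwise.

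Named genes followed a fixed rule. They were Dbh, the 12 genes in each direction with the largest change among those that passed, with places left open filled by the smallest unadjusted p at an absolute log2 difference of at least 0.5, up to 3 members of each list with the smallest unadjusted p, Xist and the Y-linked genes, and the 2 most abundant members of a cell type list that is weighed. Since 0 genes passed, all 12 places in each direction were filled by unadjusted p. Other genes named (calls of alternative fits, further liver genes, and probe sets that split the hearts) were chosen after their values were seen.

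The depth of an array has no read count. The precision depends on the 4 hearts per group and on the scaling of the arrays, with a median 95% confidence interval of 0.57 log2 units to either side as deposited and 0.41 after quantile normalization. Signal over background is given by the ratio of log intensity to log background, 1.49 to 1.59 over the arrays. The scripts were tested on simulated data, with independent normal noise at each probe set's residual SD after quantile normalization and the median shift of each array added, and with 200 of 16292 probe sets changed in each of 5 simulations. As deposited, 145 of 500 probe sets with a change of 1 log2 unit and 470 of 500 with 2 were called, with 75 false calls in all, and after quantile normalization 303 and 452, with 38 false calls. In further simulations without those changes (5 with no list changed and 5 with 1 changed), on 9126 genes, camera with a preset correlation called 4 of 120 unchanged lists as deposited and 0 of 120 after quantile normalization, and a list shifted by 0.5 was called in 5 of 5. The simulated genes vary independently apart from the array shifts, while splits of the real hearts into 4 and 4 called a median of 14 of the 24 lists, so they say little about false list calls in these data.

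Alternatives fixed beforehand were pseudocounts of 1 and 64, no filter, Present in all 8 arrays, quantile normalization, median centring, eBayes without trend and with robust estimation, array weights, the title number as fixed and as random block, title numbers 541 and 569 alone, a sex covariate, each heart left out in turn, the authors' deposited test, an unequal-variance test per probe set, an adjusted p of 0.1, the mean of a gene's probe sets, 10 and 40 Mb around Dbh and an unadjusted p of 0.05 there. Quantile normalization or median centring combined with the title number block, with sex, or with WT 3 or WT 3 and WT 4 left out were added after the data were seen. The labels do not state that replicate numbers pair hearts, and the hearts numbered 1 carry different title numbers (570 and 569), so no pairing by number was used. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.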

Results

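Gene expression was measured in 8 mouse embryo hearts at E10.5 on Affymetrix Mouse 430A 2.0 arrays. Hearts of 4 embryos lacked a working gene for dopamine beta-hydroxylase (Dbh-/-, called KO here), the enzyme that makes noradrenaline from dopamine. Hearts of 4 embryos were Dbh+/+ (WT). Each array held RNA from 1 heart, so every replicate is a separate embryo, and the number of arrays limits the precision. The values are MAS5 signals for 22690 probe sets, of which 16292 were tested, naming 9126 genes. The sample titles carry the numbers 541 (WT 3, WT 4, KO 3 and KO 4), 569 (WT 2, KO 1 and KO 2) and 570 (WT 1), which the labels leave unexplained. Between 65.2% and 71.6% of probe sets were called Present per array, and the trimmed mean signal ran from 209.8 to 316.2. Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty parted the hearts into 2 males and 2 females in each genotype. Eif2s3y signals were at least 1364 in the male hearts and at most 4.80 in the female hearts.

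Dbh itself was near the floor of the array in every heart, so it does not check the genotype labels. Its probe set was called Absent in 8 of 8 hearts, with signals of 4.06 ± 4.85 in WT and 2.51 ± 2.77 in KO (SD, n = 4 each). The log2 difference, KO minus WT, was -0.10 ± 0.16 (SE). Whether the probe set covers the part of the gene changed in the allele is not stated.

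The main comparison asked which transcripts differ between hearts of embryos without and with Dbh, that is, without and with their own noradrenaline synthesis. No gene passed the test, so the genes below are those with the smallest unadjusted p, and none of them is shown to differ. Hhip, which codes for a cell-surface protein that binds and blocks hedgehog ligands, led the higher side with a signal of 26.6 ± 25.9 in KO and 2.63 ± 2.83 in WT (SD, n = 4 each). Snai1, a transcription factor of the step by which endocardial cells become cushion mesenchyme, had signals of 26.2 ± 17.4 in KO and 6.67 ± 7.59 in WT. Fmod, which codes for a collagen-binding matrix proteoglycan, was better measured, with 201.8 ± 68.5 in KO against 93.7 ± 31.7 in WT, and Mgp, an inhibitor of matrix calcification, had 59.3 ± 19.1 against 24.6 ± 11.3. On the lower side, Nf1, a brake on Ras signalling and on the growth of heart cushions, had 26.6 ± 9.20 in KO and 58.03 ± 13.97 in WT, and Mapre1, a protein of growing microtubule ends, had 968.5 ± 250.2 against 1584 ± 469.1.

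Of 16292 probe sets, 0 passed limma's test at an adjusted p of 0.05, and 217 had an unadjusted p under 0.05, 148 higher and 69 lower in KO, where chance alone gives 814.6. The smallest adjusted p was 0.99998. After quantile normalization between arrays 0 passed and 350 were under 0.05 (182 higher and 168 lower), after median centring 0 passed and 296 were under 0.05 (123 higher and 173 lower), so the excess of higher probe sets depended on the scaling, and an unequal-variance test per probe set gave 0 and 116. The authors' own deposited p-values were under 0.05 for 282 of 22690 probe sets, 155 higher in WT and 127 higher in KO, where evenly spread p-values would give 1134.5, and 0 remained after Benjamini-Hochberg adjustment. The median 95% confidence interval reached 0.57 log2 units to either side, or 0.41 after quantile normalization. On data simulated with the spread of these arrays and independent noise, 94% of probe sets given a 2 log2 unit change were called and 29% of those given 1 log2 unit, so under that noise changes of 1 log2 unit would often be missed.

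The log2 differences of the higher genes were 1.03 ± 0.27 for Hhip, 0.92 ± 0.25 for Il18, 0.90 ± 0.26 for Myt1, 1.04 ± 0.31 for Cldn8, 0.90 ± 0.27 for Mgp, 1.05 ± 0.32 for Cldn11, 0.74 ± 0.23 for Hesx1, 1.51 ± 0.47 for Lancl2, 0.86 ± 0.26 for Snai1, 0.98 ± 0.31 for Fmod, 0.83 ± 0.26 for Prdm1 and 0.73 ± 0.23 for Cmpk2 (SE, n = 4 each). Those of the lower genes were -0.87 ± 0.28 for Oit3, -0.80 ± 0.26 for Nf1, -1.74 ± 0.57 for Igfbp1, -0.73 ± 0.25 for 2810459M11Rik, -0.58 ± 0.21 for BB283400, -0.81 ± 0.30 for Steap1, -0.69 ± 0.26 for Mapre1, -0.61 ± 0.23 for Gm5802, -0.63 ± 0.24 for Fgf18, -0.56 ± 0.21 for Bco1, -0.81 ± 0.31 for Dner and -0.60 ± 0.24 for Angptl6. Low signals make the log2 difference depend on the pseudocount: that of Hhip was 2.84 with 1 and 0.41 with 64, that of Cldn8 1.76 and 0.48, and that of Snai1 2.26 and 0.34. Igfbp1 rested on WT 3, with a signal of 842.0 there and at most 28.2 in the other 7 hearts. Lancl2 rested on WT 1 and WT 2, at 66.5 and 59.9 against 299.0 to 890.7 elsewhere, and 1 of its 2 other tested probe sets went the opposite way, as did the 1 other probe set of Nf1. The difference of Nf1 was -0.78 with the title number as a block and -0.88 after quantile normalization with that block, and that of Fmod was 0.99 and 0.89. WT 1, the only heart with its title number, adds nothing to these blocked differences.

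**Figure D1:**
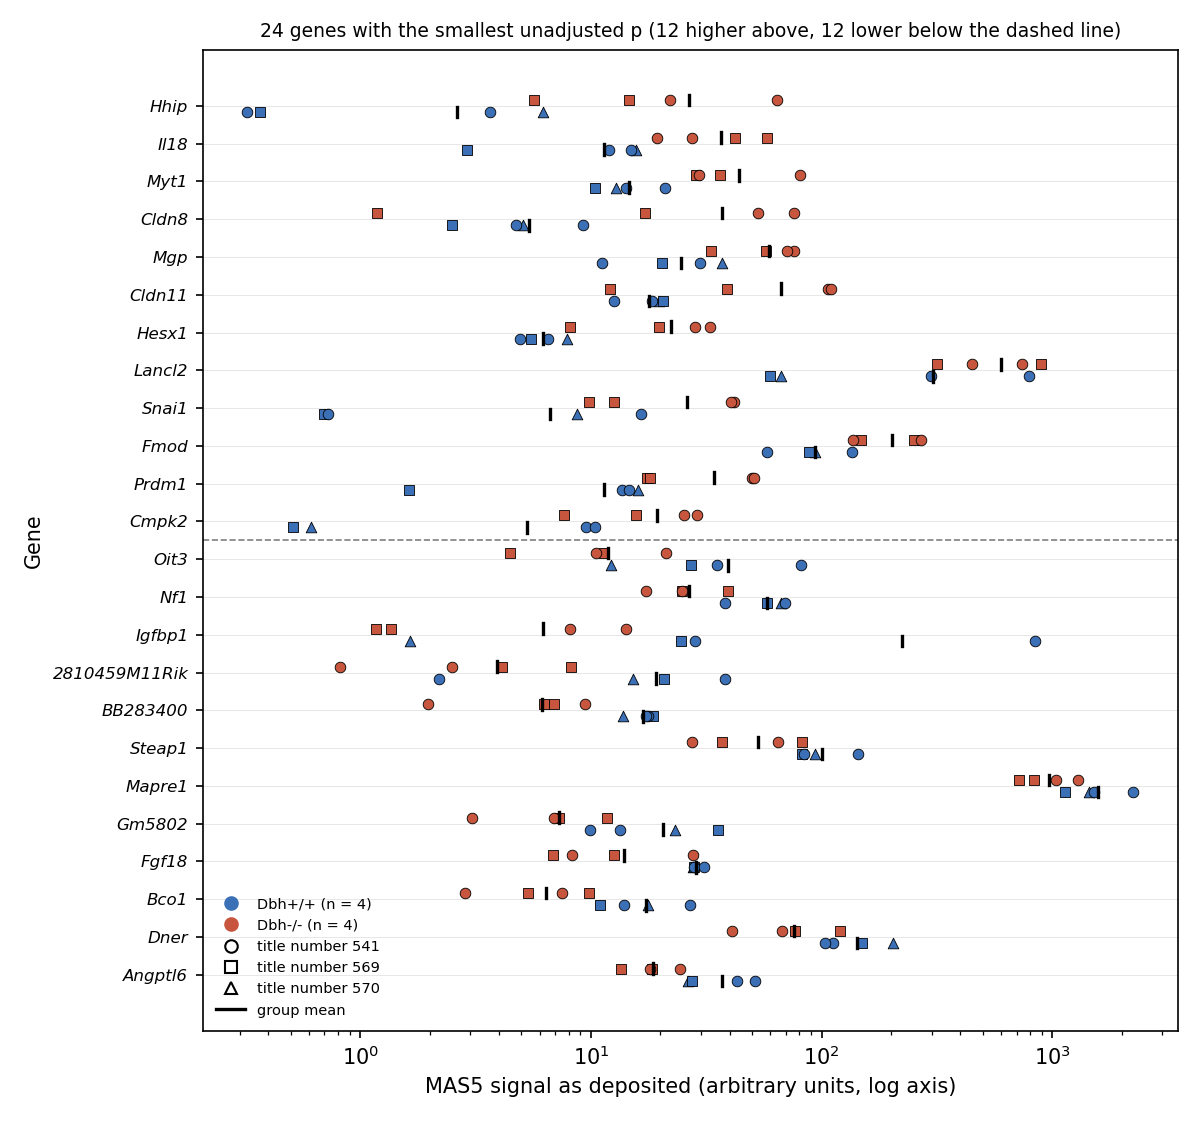
Signals of the 24 genes with the smallest unadjusted p (12 higher and 12 lower in KO) in each of the 8 hearts, on a log axis in arbitrary units, with colours for genotype, shapes for title number and bars for group means. Signals of Hhip lie between 0.32 and 6.17 in WT and between 5.68 and 64.2 in KO, while Igfbp1 reaches 842.0 in a single WT heart.

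The number of calls depended on single hearts and on the title number, mostly on values as deposited. As deposited without WT 3, limma called 72 probe sets, 71 higher in KO, among them Klf1, Gata1 and Alas2 of red blood cell formation, Pax3 and Crabp1 of neural crest, and Hoxb5. Without KO 1 it called 30, all higher in KO. With the title number as a fixed block it called 40. WT 1, the only heart with its title number, adds nothing to the genotype estimate of that fit. Of the 40, 13 were lower and included the liver genes Afp, Ttr, Apoa1 and Hnf4a, and 27 were higher and included Dlx2, Sox2 and Nefm. Within title number 541 alone (2 hearts against 2) it called 60. Within 569 alone it called 3, namely Ctr9, Tac2 and an unnamed probe set that parts the hearts by sex, but with 1 WT heart there these calls cannot part genotype from that embryo. After quantile normalization each of the first 3 of these fits called 0, and the fit within 541 called 1, an unnamed probe set that is high in KO 3 and KO 4. Limma weighs a common intensity trend against each probe set's own spread, by its prior degrees of freedom. As deposited these were infinite without WT 3, with the block and within 541, so a probe set's own spread was not used. A single extreme heart, or a few hearts that share a pattern, can then pass more easily. After quantile normalization the prior degrees of freedom were 5.23, 4.62 and 5.41. Hoxb5 and Pax3 were high in WT 3, KO 3 and KO 4, at 116.4 and 87.2 or more, and at most 22.7 and 22.1 elsewhere. For these genes, leaving out WT 3 takes away the only WT heart with the high level. Genes of these other fits were chosen after their values were seen.

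Gene lists fixed beforehand asked whether cell types or pathways of the embryonic heart shifted together. Genes of primitive and definitive red blood cells were higher in KO, with a median log2 difference of 0.67 over 21 genes, and 19 of them positive, by camera with a preset correlation only (adjusted p = 0.808 with an estimated correlation, exact score p = 0.343, and 0 members passed). Klf1, the master regulator of red cell genes, had a signal of 187.7 ± 149.6 in KO and 69.3 ± 65.1 in WT, and Ermap, a red cell membrane protein, 726.7 ± 447.5 against 365.8 ± 328.1 (SD, n = 4 each). Genes induced by low oxygen were lower in KO by the same test only, with a median of -0.21 and 24 of 25 genes negative (adjusted p = 0.835 with an estimated correlation). Without WT 4 their median was -0.02 and the test turned higher. Adm, a vessel-dilating peptide, had 58.5 ± 29.5 in KO and 132.6 ± 119.3 in WT, and Vegfa, the main growth factor of blood vessels, 162.5 ± 34.2 against 323.1 ± 282.3. In WT 4 alone Vegfa reached 735.6 and Adm 310.9.

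Of 24 lists, limma's camera with a preset correlation called 9, and with the correlation estimated from the data it called 0. The list of red blood cell genes had an adjusted p of 6.51e-17 (adjusted p = 0.808 with an estimated correlation). Also higher were neuron and neural crest genes (median 0.54, adjusted p = 1.61e-06, and adjusted p = 0.808 with an estimated correlation), branchial and skeletal muscle genes (0.45, 0.00193), macrophage genes (0.33, 0.000118) and cushion mesenchyme genes (0.19, 0.00166), the last 3 with adjusted p = 0.835 with an estimated correlation. Lower were hypoxia-induced genes (adjusted p = 8.57e-07), immediate early and heat shock genes (median -0.05, 0.00193), endothelial genes (-0.16, 0.00356) and liver and endoderm genes (-0.33, 0.00101), each with adjusted p = 0.835 with an estimated correlation. The limma test fry called 0 lists. No list member passed limma's test over all genes, and 0 passed when adjusted over the list alone. After quantile normalization camera called 7 lists, dropping branchial, immediate early and liver genes and adding oxidative phosphorylation (median 0.08, adjusted p = 0.000221, and adjusted p = 0.851 with an estimated correlation). Exact two-sided permutation tests of the mean list scores per heart after quantile normalization had their smallest p of 0.229 for red blood cell genes (Benjamini-Hochberg adjusted p = 0.971 for every list), where 4 hearts against 4 can reach 0.0286. These permutations take no account of the title number, and none of the scores were run within title numbers. The red blood cell score averaged 0.54 in the 541 hearts and -0.54 in the others, which widens the spread set against genotype.

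The remaining 15 lists were not called. Their median log2 differences were 0.03 for catecholamine synthesis, -0.01 for adrenergic receptors and cAMP signalling, -0.05 for sarcomere proteins, 0.04 for calcium handling and ion channels, -0.04 for cardiac transcription factors, -0.00 for natriuretic peptides and stress genes, 0.11 for retinoid metabolism and response, -0.01 for glycolysis, 0.05 for oxidative phosphorylation, 0.03 for the citrate cycle, 0.07 for fatty acid oxidation, 0.06 for cell cycle, -0.04 for p53 targets, 0.01 for the unfolded protein response and -0.06 for epicardial genes. The adjusted p ran from 0.173 for epicardial genes to 0.940 for fatty acid oxidation. The retinoid list is named in the study's own account of these hearts and is not independent evidence. Among its members, Rdh10, an enzyme of retinoic acid synthesis, had 209.0 ± 90.4 in KO and 121.9 ± 47.4 in WT (SD, n = 4 each). Median and mean differed in sign for adrenergic receptors (mean 0.05), sarcomere proteins (0.03), cardiac transcription factors (0.05), natriuretic peptides (0.07) and the unfolded protein response (-0.02). The camera test pointed higher for adrenergic receptors and natriuretic peptides, and lower for sarcomere proteins, calcium handling, cardiac transcription factors, the citrate cycle and the unfolded protein response.

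Within title numbers, the score of red blood cell genes was higher in KO by 0.60 in 541 and by 0.85 in 569, and that of macrophage genes by 0.33 and 0.40. Neuron and neural crest genes differed by 1.15 in 541 and by -0.17 in 569, cushion mesenchyme genes by 0.72 and -0.16, branchial genes by 0.87 and 0.09, and hypoxia-induced genes by -0.52 and 0.25. With the title number as a fixed block, WT 1, the only heart with its number, adds nothing to the genotype estimate. In that fit the median for red blood cell genes was 0.78 and 10 lists were called by camera with a preset correlation. With quantile normalization and that block the median was 0.68 and 6 lists were called. Macrophage, cushion and branchial genes were not among them, with camera adjusted p of 0.0783, 0.0686 and 0.0991. In either fit 0 lists were called with an estimated correlation or with fry. Left out singly, WT 3 raised the count to 15 lists, with the liver list then at 0.17 and called in the opposite direction (adjusted p = 1.83e-05, by camera with a preset correlation), and without WT 4 the count was 6, with 1 list lower. Without WT 4 the hypoxia list lay at -0.02, the score difference of cushion genes went from 0.25 to -0.00 and that of immediate early genes from -0.19 to -0.06, and cushion, immediate early and endothelial genes lost their calls.

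**Figure D2:**
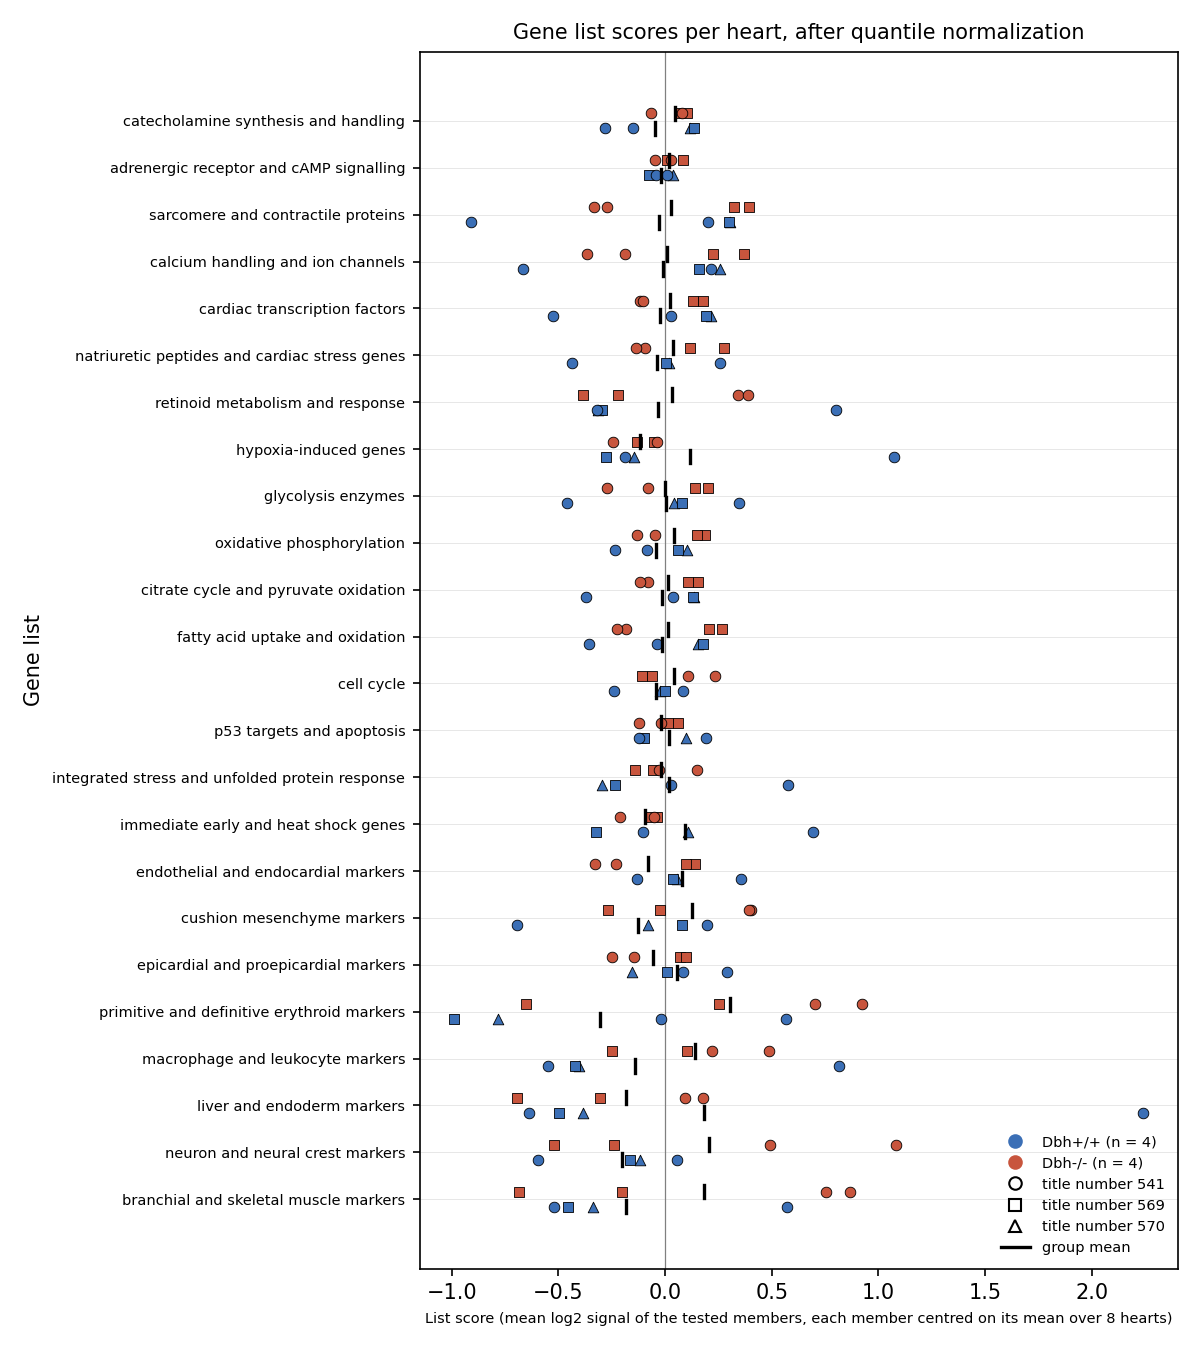
Scores of the 24 gene lists in each of the 8 hearts after quantile normalization (mean log2 signal of the tested members, each centred on its mean over the hearts), with colours for genotype, shapes for title number and bars for group means. WT 3 stands at 2.24 for liver and endoderm genes and at -0.91 for sarcomere proteins, and WT 4 at 1.07 for hypoxia-induced and 0.69 for immediate early genes.

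The liver and endoderm list was lower in KO because of 1 heart. Afp, the main serum protein of the fetal liver, had a signal of 3396 in WT 3 and at most 29.1 in the other 7 hearts, Ttr, a carrier of thyroid hormone and retinol, 1964 and at most 49.1, and Alb, serum albumin, 674.5 and at most 9.24. Further liver genes were chosen after their values were seen.

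**Figure D3:**
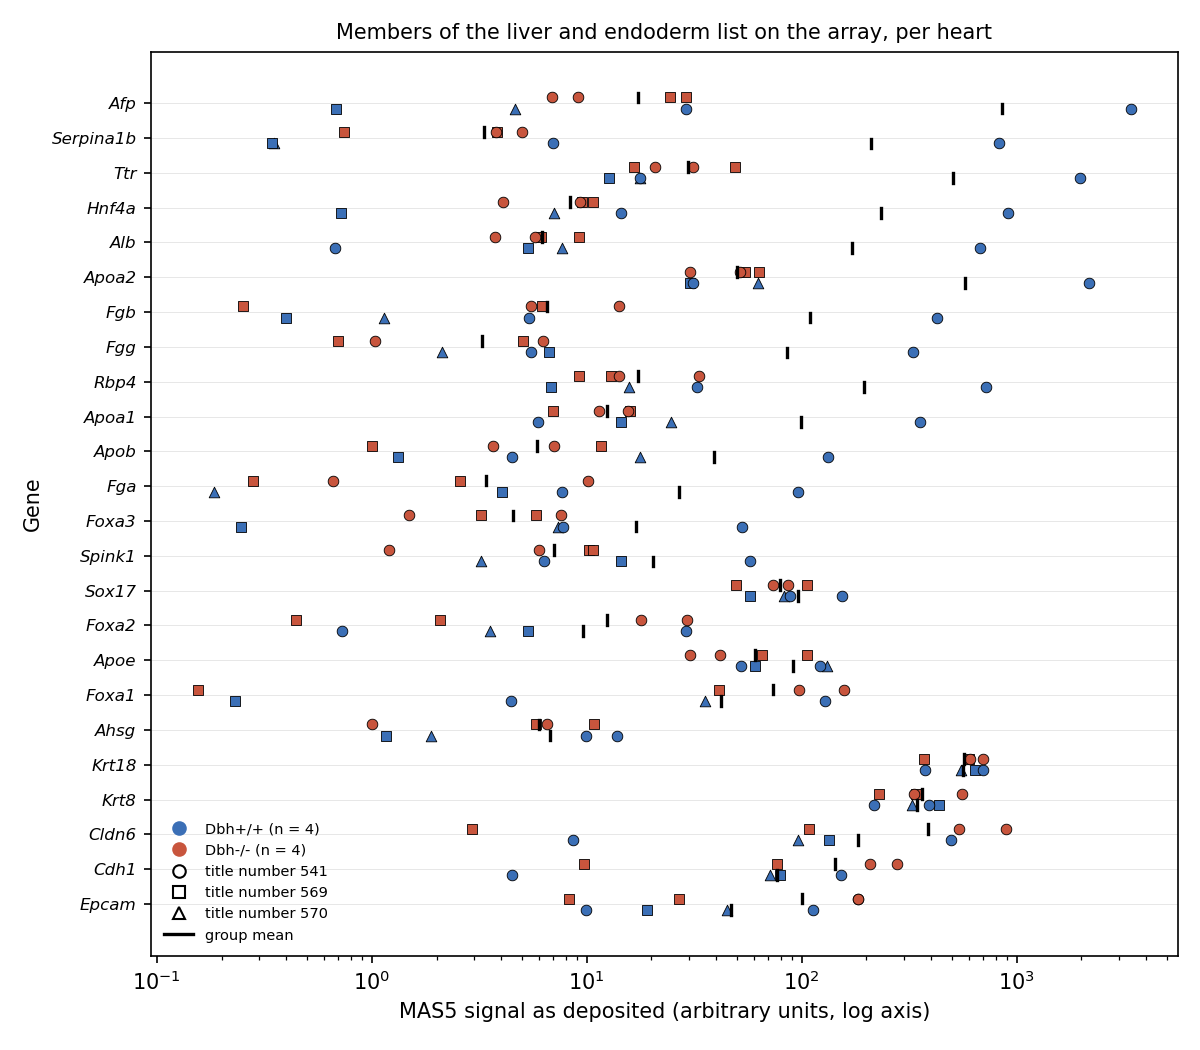
Signals of the members of the liver and endoderm list on the array in each of the 8 hearts, on a log axis in arbitrary units, with 1 point per heart, colours for genotype, shapes for title number and bars for group means. Alb reads 674.5 in WT 3 and at most 9.24 elsewhere, while Epcam, Cdh1 and Cldn6 are also high in KO 3 and KO 4.

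Terms in the deposited annotation asked the same of older pathway and ontology classes. Of 155 terms, camera called 1, phosphate transport (14 genes, median 0.27 higher in KO, adjusted p = 0.000695, and adjusted p = 0.999 with an estimated correlation). The next higher terms were porphyrin and chlorophyll metabolism, the class that holds heme synthesis (median 0.25, adjusted p = 0.0818), development (0.14, 0.138), intracellular signaling cascade (0.06, 0.653) and cell cycle (0.07, 0.885). The lower terms were MAPK signaling (median -0.07, adjusted p = 0.0712), type I diabetes mellitus (-0.05, 0.159), glycosphingolipid metabolism (-0.13, 0.378), lipid catabolism (-0.02, 0.653) and ribosome (-0.02, 0.885). After quantile normalization the 1 called term was oxidative phosphorylation (93 genes, median 0.07, adjusted p = 0.00789, and adjusted p = 0.998 with an estimated correlation).

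The genotype differences within title numbers 541 and 569, which share no heart, were compared across the 9126 genes. They correlated at r = -0.15 (Spearman's rho = -0.15), and 45.9% of genes had the same sign. Across 18 arrangements of the genotype labels within the 2 title numbers, 14 gave an r as high, the highest other being 0.32. Genes are not independent replicates, and 569 holds 1 WT heart.

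DNA next to a targeted allele can stem from another strain, which the labels do not state, and genes near Dbh on chromosome 2 were compared with the rest. Within 20 Mb of Dbh, 0 of 180 genes had a limma unadjusted p under 0.01, against 29 of 8937 elsewhere (Fisher's exact test, two-sided p = 1). At an unadjusted p under 0.05 the counts were 1 of 180 and 130 of 8937 (Fisher's exact test, two-sided p = 0.524). The confidence interval of the odds ratio ran from 0 to 6.78 at the limit of 0.01 and from 0.0095 to 2.17 at 0.05. With so few genes under either limit, a higher share near Dbh is not excluded, and the test cannot decide the question.

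Array quality did not differ between genotypes by more than the spread between hearts. The ratio of 5' to 3' signal of the Gapdh control was 0.717 ± 0.0295 in KO and 0.748 ± 0.0365 in WT (SD, n = 4 each; exact two-sided permutation p = 0.229), the smallest p of 8 measures (adjusted p = 0.914). Between title number 541 and the other hearts the smallest exact permutation p was 0.114 (adjusted p = 0.457), for the Gapdh and actin ratios. Within 541, WT 3, KO 3 and KO 4 had actin ratios of 0.407, 0.390 and 0.401, the lowest of the 8 hearts, and WT 4 had 0.517.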

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

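The tests of liver tissue, array brightness, tissue from outside the heart, genotype and red blood cells were chosen after the results were seen, and their thresholds were also set then. A first form of the liver test asked that most of the 16 tested members lie at least 1 log2 unit above every other heart in WT 3, and 7 did, so that form was not met. It was replaced, after the values were seen, by a count over all 24 members on the array, with a minimum of 5. A comparison of the 541 hearts with the others, first used for tissue from outside the heart, was replaced because 541 holds 2 hearts of each genotype.

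Single hearts lay far from the other 3 of their group for 14 of 280 groups tested (24 lists, 108 genes and 8 quality measures in each genotype), and chance alone gives about 1 in 20 groups, that is 5%. WT 3 accounted for 5 of them. Hnf4a read 912.7 there (0.717 to 14.4 in the other WT hearts), Coro1a 332.5 (34.5 to 35.8), Myh7 305.9 (3576 to 4836), Myl2 1728 (6187 to 7147), and the liver and endoderm list score was 2.30 as deposited (-0.80 to -0.27). WT 4 accounted for 4, with Stc2 at 116.9 (14.8 to 19.97), Msx1 at 2.92 (55.8 to 74.3), Meox1 at 3.23 (27.9 to 29.1) and Fgf18 at 30.8 (27.6 to 28.1). The others were Sox2 at 46.6 (5.49 to 8.19) and Kcnj2 at 11.4 (0.697 to 2.03) in WT 1, Prdm1 at 1.62 (13.6 to 15.9) in WT 2, Isl1 at 234.9 (1340 to 1689) in KO 1, and Gch1 at 9.37 (30.8 to 31.5) in KO 4. No quality measure stood out in this way. The ratio also flags small gaps where the other 3 hearts lie close together, as for Fgf18. All signals of Kcnj2 and Prdm1 given here lie under the pseudocount of 16.

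Whether the genotype difference itself differed between title numbers 541 and 569 was asked by limma's test of the interaction in 7 hearts. As deposited it called 38 probe sets, with infinite prior degrees of freedom, so a probe set's own spread was not used. After quantile normalization the interaction test called 0, with 956 at an unadjusted p under 0.05, and after median centring 0, with 874. The prior degrees of freedom were then 4.88 and 5.43. Title number 569 holds a lone WT heart, so the interaction test cannot part a difference between title numbers from that embryo.

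Liver transcripts in WT 3 may come from liver tissue carried over with the heart. Of the 24 list members on the array, 14 lay at least 1 log2 unit above every other heart in WT 3, and 0 did so in any other heart. They include Afp, Alb, Ttr, Apoa2 (2177 against at most 63.1) and Fgb (428.0 against at most 14.1). Brightness of the array is argued against, since after quantile normalization the list score of WT 3 still lay 2.06 above the next heart. No biological explanation was tested, because a single heart of a group gives none.

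The 5 lists higher in KO (red blood cell, macrophage, neuron and neural crest, branchial and cushion genes) could reflect genotype or the mix of tissue in each sample. WT 3, KO 3 and KO 4, which also stand apart in RNA quality ratios and on the first principal component, had the 3 highest scores for all 5 lists after quantile normalization. Among them were branchial (0.57, 0.76 and 0.87), red blood cell (0.57, 0.92 and 0.70) and macrophage genes (0.82, 0.49 and 0.22). Of these 3 hearts 2 are KO. Mean brightness hardly differed between genotypes, with a trimmed mean signal of 264.6 ± 58.3 in KO and 264.6 ± 37.8 in WT (SD). This leaves brightness little room as the whole cause. The median of each list after quantile normalization was at least 0.761 of that as deposited, which such equal means largely fixed beforehand. The branchial list lost its call (camera adjusted p = 0.297), as did the macrophage and cushion lists with the title block added. Against more tissue from outside the heart in KO, or for it, the sarcomere score (higher in KO by 0.053, SD 0.59 in WT and 0.38 in KO) decides nothing. The test of genotype asked whether all 5 lists were higher in KO by over 0.1 in both title numbers. After quantile normalization 2 (red blood cell and macrophage) were. Neuron (-0.22) and cushion genes (-0.22) were lower in KO within 569, where WT has 1 heart. Genotype could also act on some of the 5 lists only, so this outcome does not count against it. Genotype and tissue cannot be told apart with so few hearts.

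The red blood cell list may mark more red blood cells in the KO hearts, which its most abundant genes cannot decide. Hbb-bh1 and Hbb-y, embryonic globins, were higher by a mean of 0.082 against a list median of 0.67. Both lie in the top 1% of probe sets, where the array may not measure more. More red cells and a change in red cell genes cannot be told apart here.

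Other splits of the 8 hearts into 4 and 4 (35 in all, the real one included) do not let chance be excluded for the counts above 0. For probe sets called, the real value of 0 is matched by all 35 splits whatever they hold, which says nothing (highest other 488). As many reached an unadjusted p under 0.05 in 28 (217 and 6919) or, after quantile normalization, in 25 (350 and 3579), as many lists were called in 32 (9 and 20) or, after quantile normalization, in 31 (7 and 20), and as many terms in 33 (1 and 15). The split of the 541 hearts from the others called 338 probe sets as deposited and 570 after quantile normalization, which points to a structure of the samples. That split had the most calls of all after quantile normalization. As deposited, the split of WT 3, KO 2, KO 3 and KO 4 from the rest had the most (488, but 26 after quantile normalization). WT 4 of 541 lies at -23.1 on the first principal component with the other hearts, and WT 3, KO 3 and KO 4 at 30.5 to 35.2. Values blocked on the title number and within it stand in the comparisons above. The splits take no account of the title number, so those along this structure can raise the counts set against genotype. For these counts no splits within title numbers were run.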

How the results depend on the processing

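Quantile normalization or median centring combined with the title block, with sex, or with WT 3 or WT 3 and WT 4 left out was chosen after the results were seen. Changes of sign between 2 values that were both not called are counted as the same below. The cause was not tested for any change, except that a single title number leaves fewer hearts.

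Probe sets called (0 in the report) were 2 when Present in all 8 arrays was required (Ctr9 and Lancl2), 40 with the title number as fixed block, 60 in 541 alone, 3 in 569 alone, 11 with a sex covariate, 282 at the authors' unadjusted p under 0.05, 1 after quantile normalization without WT 3 and WT 4 (Lancl2), and 0 to 72 with single hearts left out (72 without WT 3, 30 without KO 1). The other 22 settings left the count as it was. As deposited, the median difference of all tested probe sets was 0.11 in 541 alone and 0.01 in all hearts. The as-deposited fits with 40, 60 and 72 calls had infinite prior degrees of freedom. These were 503.4 with a sex covariate and 27.37 in the main fit.

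Lists called (9) were 4 with array weights, 3 in 569 alone, 14 after quantile normalization without WT 3, 0 with an estimated correlation, 0 with fry, and 6 to 15 with single hearts left out (15 without WT 3). Terms called (1) were 2 with a pseudocount of 64, with no filter, with Present in all 8 arrays, in 541 alone, in 569 alone and after quantile normalization without WT 3 and WT 4, 3 with robust eBayes, and 1 to 5 with single hearts left out (5 without WT 3). They were 0 with median centring, with array weights, with median centring and the title block, with quantile normalization, the title block and sex, after quantile normalization without WT 3, and with an estimated correlation.

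In 569 alone, where the lone WT heart is assumed to vary like the KO hearts, 6 list medians reversed: hypoxia 0.27, immediate early 0.25, endothelial 0.18, liver 0.061, cushion -0.22, and neuron and neural crest -0.21. The Dbh level passed its single unadjusted test there at -0.50, where 1 WT heart cannot part genotype from that embryo, and ran from -0.19 to 0.05 with single hearts left out, in signals near the floor. After quantile normalization without WT 3, natriuretic genes were at -0.18 and liver genes at 0.13. After quantile normalization without WT 3 and WT 4, hypoxia was at 0.060, fatty acid oxidation at -0.12, integrated stress at 0.21 and liver at 0.24. With single hearts left out, medians ran from -0.44 to 0.17 for liver (0.17 without WT 3, called in the opposite direction), -0.35 to -0.020 for hypoxia (-0.020 without WT 4, where the test turned higher), -0.16 to 0.10 for integrated stress, -0.22 to 0.15 for calcium handling (0.02 without KO 3) and -0.23 to 0.20 for sarcomere (0.20 without KO 4).

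Across 670 list settings, 573 were counted as the same, 42 lost the call, 38 gained one and 17 reversed. The 573 include changes of sign between values that were both not called. In all, 21 of the 24 lists had a median of the other sign in at least 1 setting. Red blood cell genes were called in 28 of 28 settings with camera's preset correlation (medians 0.29 to 1.25), macrophage genes in 25 of 28. With an estimated correlation neither was called in any of the 5 fits where it was tried. Of 3200 settings of named genes, 3141 were the same and 59 gained a call, and the 24 genes with the smallest p kept their sign in every setting run, which their selection on the same hearts largely fixes. The agreement between title numbers kept its outcome in every setting run (-0.24 to -0.03 with single hearts left out). So did array quality (smallest adjusted permutation p 0.457 to 0.96 with single hearts left out). Genes near Dbh did too, though so few genes had a small p that this outcome could hardly change. Fisher's p there was 0.268 to 1 with single hearts left out. It was lowest, 0.0783, with the title number as fixed block, where 0 of 180 genes near Dbh were under 0.01, so their share was not higher. Signal over background (ratio of log intensity to log background) was 1.49 to 1.59. The median 95% confidence interval reached 0.57 log2 units to either side as deposited and 0.41 after quantile normalization at the same number of hearts, so the scaling of the arrays affects the precision too.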

Other observations

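The tests of probe sets with 2 levels were chosen after the results were seen, as were the genes named here.

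Some probe sets split the 8 hearts into 2 separate levels. Of 23 with a gap of at least 1.5 log2 units, 7 followed sex and 8 parted WT 3, KO 3 and KO 4 from the rest. Those 8 include Hoxb5 and Hoxc4, which set position along the body axis (Hoxc4 384.0 to 850.3 against 35.4 to 86.9), Pax3 of neural crest and somites (87.2 to 203.6 against 0.891 to 22.1), and Epha3, a guidance receptor of cushions and nerves. The same 3 hearts held the lowest sarcomere scores after quantile normalization (-0.91, -0.27 and -0.33, others 0.20 to 0.39) and one end of the first principal component, which carried 40.9% of the variance. They also held the lowest 5' to 3' ratios of the actin control (0.407, 0.390 and 0.401 in WT 3, KO 3 and KO 4, others 0.483 to 0.527) and of the Gapdh control (0.694, 0.686 and 0.702, others 0.724 to 0.775). A different amount of tissue from outside the heart and a difference in RNA quality are candidate explanations. Other probe sets were tested for 3 of the genes, and the same hearts differed there by 1.85 log2 units in Mpzl2, 1.65 in Slc14a1 and 0.49 in Epha3, with median signals of at most 9.45, 25.7 and 9.79. These medians are over all 8 hearts, of which 5 held the low level, so low medians were likely beforehand. They do not count against a change in the level of the whole gene. The differences are sizes without sign. Those in Mpzl2 and Slc14a1 are large enough for such a change, and that in Epha3 leaves it open. The candidate explanations cannot be told apart.

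Another 8 split the hearts in other ways. Ctr9, a part of the RNA polymerase-associated PAF1 complex, read 15.4 to 37.2 in WT 1, KO 1 and KO 2 and 1049 to 3278 in the other 5 hearts, while its 3 other tested probe sets differed by at most 0.27 log2 units. For Ctr9, Wnt5a and Anxa2, where another probe set had a median signal of 81.9, 669.9 and 2415, the largest such difference was 0.37, which argues against a change in the level of the whole gene. For Lancl2 it was 0.087, but the median signal there was at most 12.3, so a change of the whole gene stays open. A sequence variant under the probe set or a change in part of the transcript could leave 1 probe set apart from the others. Neither was tested, and no strain is given in the labels.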
